A study of Mus musculus with 15 samples.

How the data were processed

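The data are peak lists from FLAG ChIP-seq of mouse osteoblasts, 1 list per library for 12 of the 15 samples; the other 3 samples are input DNA and have no list here. Per the labels, primary osteoblasts came from calvaria of postnatal day 1 mice, and MC3T3-E1 cells (passages 5 to 10) were cultured for 1 week in osteogenic medium with BMP2 at 10 ng/ml, a bone-inducing growth factor, beta-glycerophosphate at 10 mM and a phosphate of ascorbic acid at 50 ug/ml. Per the labels, chromatin was fixed with formaldehyde, sonicated and pulled down with the M2 antibody against FLAG. Each deposited list has 3 columns, chromosome, start and end, and the authors' positions are the only values in it: no score, fold or read count is given, so total reads and the depth behind a peak are unknown. The genome build is mm9, per the submitters' processing notes. The aligner, the peak caller and its threshold are not given in the sources used here. Per the labels, peaks of primary Sp7 and of the wild-type control were called against 1 primary input, those of cell line Sp7 and Dlx5 against a first cell line input, and those of Sp1 and Sp7mut against a second; the input of the GFP control is not stated. Lists were made per library, not from pooled replicates. The labels do not say whether replicates came from separate cultures or litters, so their spread may be technical. Rows are not in genomic order, and the rule behind their order is not stated.

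Groups and replicate numbers were taken from the sample titles. Peaks overlapped when they shared at least 1 bp. A region counted for a group when merged peaks of that group held a peak of each of its 2 replicates, and when it did not overlap a peak of the FLAG control of the same cell system. Overlap between groups is the percentage of regions of a group that overlap a region of another, with 95% Clopper-Pearson intervals, which cover counting error only. Chance was measured by placing regions at random within their chromosomes, between the outermost peaks of all lists, 1000 times (200 times for alternatives), and by shifting them together by 50 kb to 5 Mb. Random placement ignores that peaks gather in open chromatin, so fold over chance is high for any pair of factors. It is also held down where a share nears its ceiling, so it was not used to rank pairs. Shares with different partners were compared on the 19 autosomes and X with an exact two-sided sign test over these 20 chromosomes, adjusted by Benjamini-Hochberg over 30 contrasts. Chromosomes are not replicate libraries, so this test speaks of these lists, and the range over the 4 pairs of single lists is given as the replicate spread.

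Longer lists meet more regions, so lists were also compared at the length of the shortest cell line list, 5019 regions. Without a score, the ranking fixed before the data were examined was peak width, as a percentile averaged over the replicates. Row order, averaged in the same way, was added after seeing the data, because it followed replicate overlap and width did not; both are reported where they differ. Named regions were fixed as the 10 top regions of each group and the top 5 of each of 6 classes (Sp7 with and without Dlx5, Dlx5, Sp1 and Sp7mut without Sp7, and Sp7 in both cell systems) by width; those by row order were added after seeing the data. Coordinates are 1-based mm9. The other alternatives were an overlap of at least 50% of both peaks, the wider 50% of the peaks of each list, control peaks kept, and each replicate left out, and, after seeing the data, the earlier 50% of each list, the first 1000 regions, the first 2097 (the length of the primary Sp7 list) for differences between contrasts, and the contrasts between partners. Protein-coding genes per chromosome, 21627 in all, were counted in a gene table of GRCm38.p6, with chromosome lengths taken as the span of peaks; none of its coordinates were used. Correlations were tested with 100000 permutations of the chromosomes.

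The overlap code was tested on simulated lists of 6063 regions with 200 placements: planted overlaps of 0, 10, 30 and 60% were estimated as 0.121, 10.0, 29.9 and 59.7%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Of the planned analyses, 3 were not run because they need the sequence or gene annotation of mm9, which was not used here: the share of peaks near transcription starts, motif enrichment, and genes near regions with the 15 gene lists fixed for them. Scores at regions could not be compared, and row order was described in their place.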

Results

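Sites bound by FLAG-tagged transcription factors were mapped by ChIP-seq in mouse osteoblasts. In primary calvarial osteoblasts of postnatal day 1 C57BL/6 pups, the tagged protein was Sp7, carried on both alleles of the gene under the genotype name BioFL. Sp7 (Osterix) is a zinc finger factor required for osteoblast differentiation. In MC3T3-E1, a mouse calvarial pre-osteoblast line grown for 1 week in osteogenic medium, the tagged proteins were Sp7, Dlx5, Sp1 and a mutant labelled Sp7mut. Dlx5 is a homeodomain factor of skeletal development, and Sp1 is a widely expressed zinc finger factor that binds GC-rich sites. Each of these 5 groups had 2 libraries. A wild-type library in primary cells and a GFP library in the cell line, both taken through the same FLAG pulldown, gave the antibody background, with 1 library each. The mutation in Sp7mut and the way the factors were expressed in the cell line are not stated in the labels.

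Tagged factors gave many more peaks than the FLAG controls in both cell systems. In primary osteoblasts, Sp7 had 2939 ± 386 peaks (SD, n = 2) against 183 in the wild-type control. In MC3T3-E1 cells, Dlx5 had the longest lists, with 34992 ± 6728 peaks (SD, n = 2). Sp1 had 19380 ± 12488, Sp7mut 12675 ± 3048 and Sp7 12344 ± 8882 peaks (SD, n = 2 each), against 269 in the GFP control. Every tagged list held at least 14.6 times as many peaks as the control of its cell system. The replicates of Sp7 in the cell line had 18624 and 6063 peaks and those of Sp1 10549 and 28210, so the numbers of these factors differed by less than the spread within them. With 2 lists against 2, an exact two-sided permutation test cannot fall below p = 0.333, and no test of peak numbers was made. Median peak widths of the tagged lists lay between 147 and 195 bp, and were 153 bp in the wild-type and 134 bp in the GFP control. The lists carry no read counts or scores, so the depth of the libraries is unknown.

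**Figure D1:**
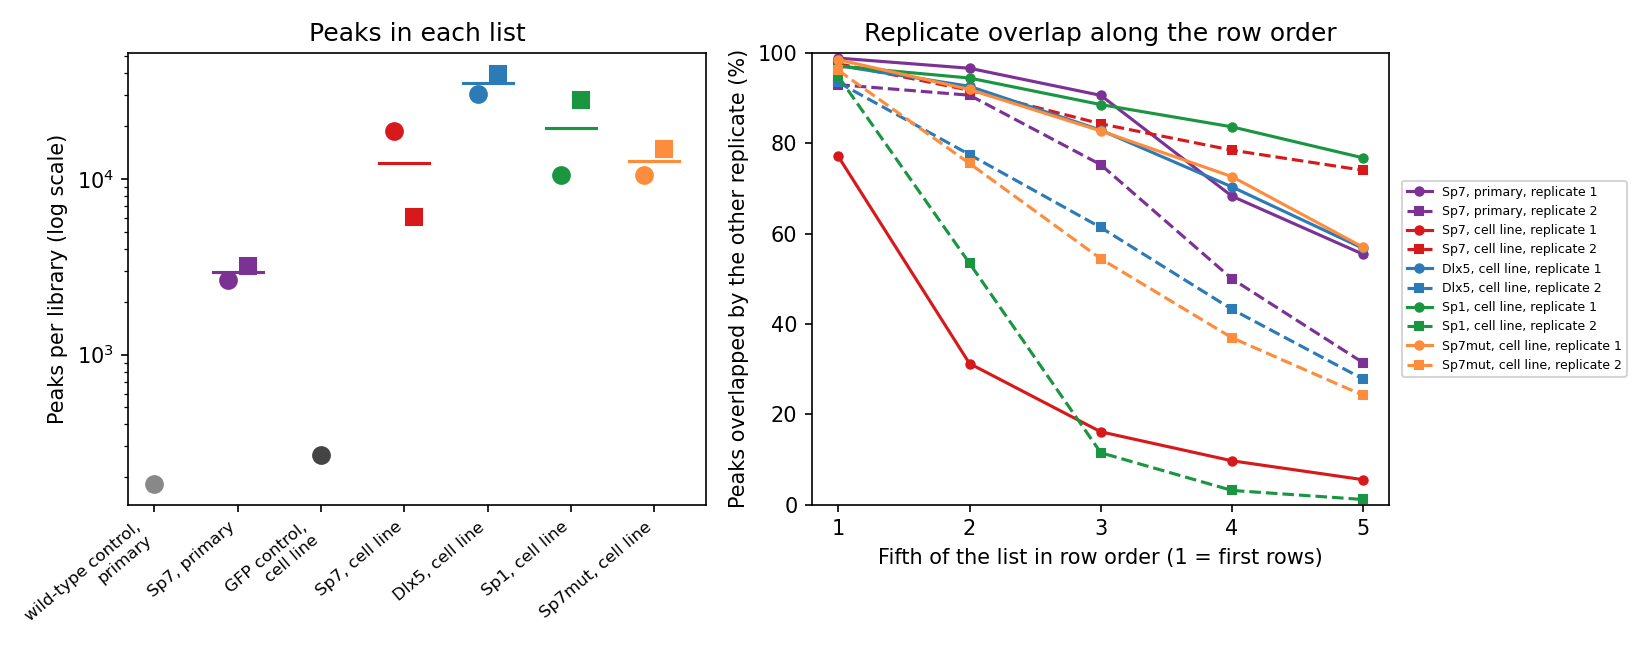
Left, peaks per library on a log axis, with replicate 1 as circles, replicate 2 as squares and the mean of 2 libraries as a line; the controls have 1 library each. Right, the percentage of peaks overlapped by the other replicate in each successive 20% of the list, taken in row order, for the 5 tagged groups (solid lines, replicate 1; dashed lines, replicate 2). Overlap falls along the rows of every list, in Sp1 replicate 2 from 94.8% to 1.15%.

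Replicates found largely the same sites, up to the length of the shorter list. In primary osteoblasts, 82.0% of the Sp7 peaks of replicate 1 overlapped a peak of replicate 2, and 68.1% the other way round. For Dlx5 the shares were 80.0% and 60.7%, and for Sp7mut 80.6% and 57.5%. In cell line Sp7, 85.2% of the 6063 peaks of replicate 2 were met by replicate 1, but only 27.9% of the 18624 peaks of replicate 1 were met by replicate 2. Sp1 was as uneven, at 88.1% of replicate 1 and 32.8% of replicate 2. Each share was at least 121 times that of peaks placed at random on the same chromosome (permutation p = 0.001 each, the smallest that 1000 placements can give).

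The order of rows in the lists followed how often a peak was found again, and peak width did not. In Sp7 replicate 1 of the cell line, 77.1% of the peaks in the first 20% of rows were met by replicate 2, against 5.53% in the last 20%. Ranked by width, the successive 20% parts of the same list lay between 21.7% and 33.6%. Across regions found in both replicates, row positions in the pair of lists had a Spearman correlation of 0.680 in cell line Sp7 and up to 0.878 in Sp1. These are correlations across regions, which are not independent replicates.

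Background of the FLAG antibody took a small part of each list and, in some groups, a larger part of its start. Wild-type control peaks covered 3.26% and 3.21% of the Sp7 peaks in primary osteoblasts, but 30 and 36 of the first 100 rows. In the cell line, GFP control peaks covered between 0.304% and 1.69% of peaks, but 18 and 23 of the first 100 rows of the Sp1 lists and 3 and 15 of those of Sp7mut, against 3 and 0 for Sp7 and 7 and 0 for Dlx5. Of the 183 wild-type control peaks, 96 (52.5%) overlapped a GFP control peak, and 26 were met in all 12 lists. Regions over a control peak were left out of what follows. This left 2097 regions found in both replicates for Sp7 in primary osteoblasts, and 5019 for Sp7, 23688 for Dlx5, 8942 for Sp1 and 8203 for Sp7mut in MC3T3-E1. These regions lay close together: 47.5% of Dlx5 regions and 19.9% of cell line Sp7 regions had another region of their group within 10 kb, where random placement gave 18.9% and 4.72%.

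The series' title places Sp7 beside Dlx factors, and the set of factors asks how Sp7 sites relate to those of Dlx5 and of Sp1, a relative of Sp7. Most Sp7 regions in MC3T3-E1 cells were also Dlx5 regions. Of the 5019 Sp7 regions, 84.4% (95% Clopper-Pearson interval 83.4 to 85.4) overlapped a Dlx5 region, and 30.3% (29.1 to 31.6) overlapped an Sp1 region. The share with Dlx5 was higher on 20 of 20 chromosomes (exact two-sided sign test p = 1.91e-06, 3.01e-06 after Benjamini-Hochberg adjustment over 30 contrasts). The Dlx5 list was the longest and also met more by chance. Seen from the partners, 18.0% of Dlx5 regions and 17.1% of Sp1 regions met an Sp7 region. Relative to random placement the overlaps were 157-fold for Dlx5 and 154-fold for Sp1, but these cannot be compared, because a share near its ceiling holds down the value for Dlx5. At 5019 regions per group they were 431 and 192 in row order and 115 and 119 by width. With replicate 1 of every group left out, so that each region needed a peak of replicate 2 alone, the share with Sp1 was 61.4% and the difference from Dlx5 fell from 54.1 to 23.4 percentage points.

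At the start of the lists the partners parted. Among the first 5019 regions of each group in row order, 46.8% of Sp7 regions met a Dlx5 region and 20.4% an Sp1 region, a difference of 26.3 percentage points in the same direction on 20 of 20 chromosomes (exact sign test p = 1.91e-06). Among the first 1000 regions, the shares were 55.2% and 13.1%. Single libraries, compared over their first 2500 rows, gave 37.8% to 52.7% for Sp7 with Dlx5 and 14.4% to 22.6% for Sp7 with Sp1 over the 4 pairs of lists, so the difference was larger than the spread between replicates. Taking the top 5019 regions by width in place of row order, the ranking fixed before the data were examined, gave 16.5% and 15.9%, a difference that did not pass the test (higher with Dlx5 on 13 of 20 chromosomes, exact sign test p = 0.263). Sp7 and Dlx5 were called against the same input library and Sp1 against another.

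**Figure D2:**
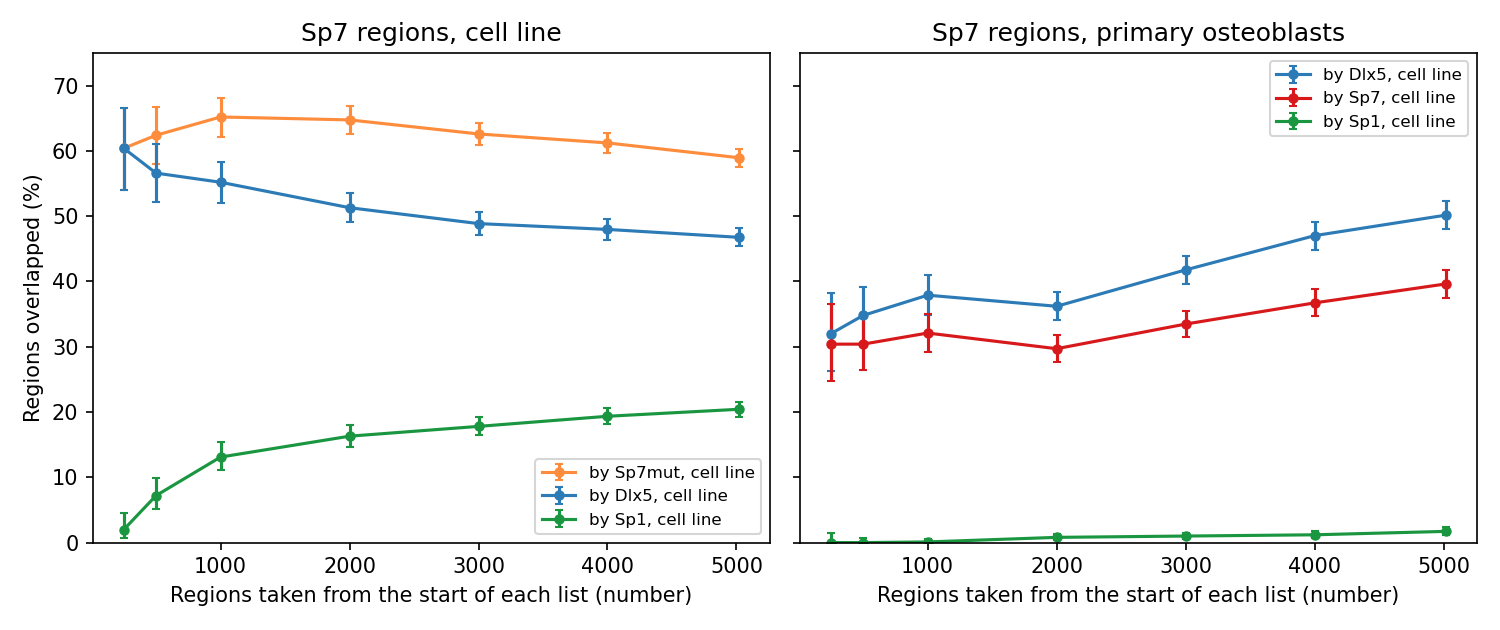
Percentage of Sp7 regions overlapped by regions of other groups (vertical axis) when only the first regions of each list in row order are kept (horizontal axis, number of regions), for the cell line (left) and primary osteoblasts (right, at most 2097 Sp7 regions); bars are 95% Clopper-Pearson intervals. In the cell line, overlap with Dlx5 runs from 55.2% at 1000 regions to 46.8% at 5019, and overlap with Sp1 from 13.1% to 20.4%.

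Sp7 regions with a Dlx5 region differed from those without in where they stood and in what else met them. There were 4237 Sp7 regions with a Dlx5 region and 782 without. Of the former, 19.2% were also Sp7 regions in primary osteoblasts, against 2.17% of the latter. From the first to the last 20% of the Sp7 regions in row order, the share with Dlx5 fell from 97.2% to 69.9%. The share with primary Sp7 fell from 46.0% to 5.98% in the same way. Regions with and without Dlx5 were not compared at matched row positions. Sp7 regions with an Sp1 region had Dlx5 less often (75.5%) than those without Sp1 (88.3%), on 20 of 20 chromosomes, and among the first 5019 regions these shares were 16.1% and 54.6%. Over all Dlx5 regions, 11.6% met an Sp1 region (28.9% without replicate 1 of each group), from 8.87% in the first 20% of rows to 16.2% in the last. Sp1 regions met Dlx5 most often at the start of their list, at 39.2% in the first 20% and 25.8% to 30.8% in the later parts. With both lists shortened to 1000 regions, 2 Dlx5 regions (0.2%) met an Sp1 region. Random placement gave 0.015% (permutation p = 0.0149), so this small overlap still lay above it.

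Peak centres of Sp7 and Dlx5 lay within the range of distances seen between replicates at the start of the lists. Only the first 5019 peaks of each list outside control peaks, or all where there were fewer, were measured. The median distance between midpoints of overlapping Sp7 and Dlx5 peaks was 17.5 to 21 bp over the 4 pairs of lists. Between replicates of a group it was 14.5 to 23 bp. For Sp7 and Sp1 it was 23.3 to 32.5 bp. These ranges were not tested against one another.

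Among the 10 cell line Sp7 regions highest in the list, all 10 were Dlx5 and Sp7mut regions, all 10 were Sp7 regions in primary osteoblasts, and 2 were Sp1 regions. The top 3 were chr15:97859520-97859677, chr19:24794066-24794246 and chr19:23458791-23458957 (mm9), and none of the 3 was an Sp1 region. The same 3 sites stood among the top 4 Dlx5 regions and the top 4 Sp7mut regions. Of the Dlx5 regions without Sp7, the highest was chr17:45185309-45185505, which was an Sp7 region in primary osteoblasts. Of the 10 highest Sp1 regions, led by chr11:51813981-51814218 and chr8:112217166-112217342, 7 were cell line Sp7 regions, 4 were Dlx5 regions and 0 were Sp7 regions in primary osteoblasts. By width, the ranking fixed beforehand, the 10 leading cell line Sp7 regions, from chr6:97160328-97160823 on, held 9 Dlx5, 5 Sp1 and 0 primary Sp7 regions. The Sp7 region without Dlx5 that ranked highest by width, at chr8:86725312-86727660, spanned 2349 bp and was also an Sp1 and an Sp7mut region. The Dlx5 region that ranked highest by width, chr5:106160131-106160820, was met by none of the other groups, nor was that of Sp1, chr1:173217690-173218190. No annotation of mm9 was used here, so the genes at these positions are not named.

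**Figure D3:**
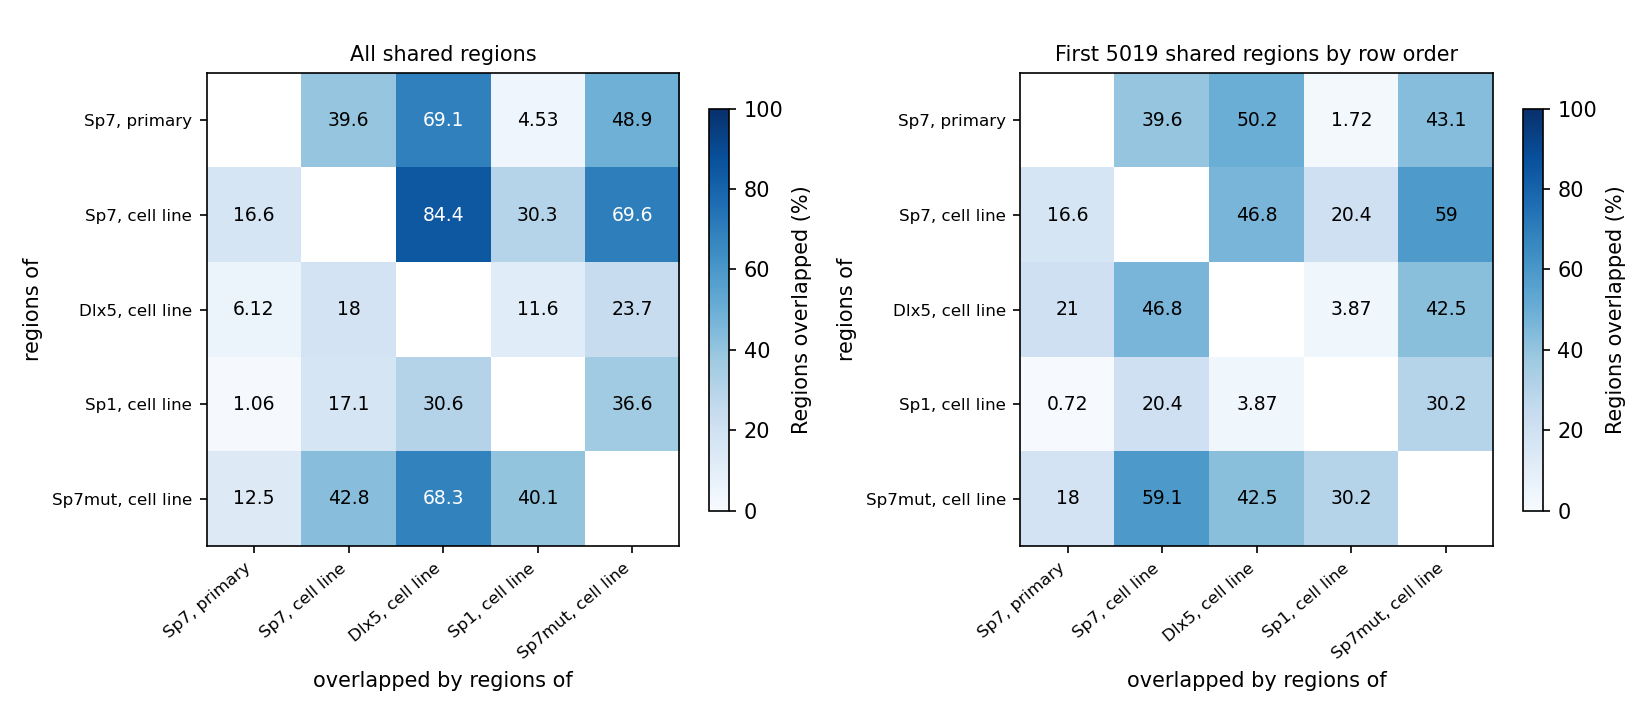
Percentage of the regions of each group (vertical axis) overlapped by regions of each other group (horizontal axis), over all regions found in both replicates (left) and over the first 5019 of each group in row order (right; all 2097 regions of primary Sp7). Sp7 and Sp7mut met most often at equal length, at 59.0% and 59.1%, and Dlx5 and Sp1 met at 3.87%.

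Sp7mut shared most of its leading regions with Sp7. Among the first 5019 regions of each, 59.1% of Sp7mut regions were Sp7 regions, 42.5% were Dlx5 regions and 30.2% were Sp1 regions. The share with Sp7 exceeded that with Sp1 by 28.8 percentage points, on 20 of 20 chromosomes (exact sign test p = 1.91e-06). Single lists of that length gave 55.8% to 57.6% for Sp7mut with Sp7. Over all regions, 69.6% of Sp7 regions were met by Sp7mut, while 42.8% of the 8203 Sp7mut regions were met by Sp7 and 40.1% by Sp1. The difference of that last pair did not pass the test (higher with Sp7 on 11 of 20 chromosomes, lower on 8, exact sign test p = 0.648). The shares over all regions moved when a replicate of every group was left out, a step that also drops the need for a second peak and changes the length of the lists: without replicate 2 39.6% of Sp7 regions met Sp7mut and 70.2% of Sp7mut regions met Sp7, and without replicate 1 67.9% of Sp7mut regions met Sp1, which turned the difference between Sp7 and Sp1 to -36.3 percentage points.

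Sp7mut regions overlapped Sp1 regions more often than Sp7 regions did. At equal length in row order the shares were 30.2% for Sp7mut and 20.4% for Sp7, with Sp7mut higher on 19 of 20 chromosomes (exact sign test p = 4.01e-05). Over all regions they were 40.1% and 30.3%, and over the top 5019 regions by width 24.8% and 15.9%, with Sp7mut higher on 20 of 20 chromosomes each time. Of Sp7 regions without Sp7mut 13.9% met Sp1, and of Sp7mut regions without Sp7 41.7% did. Overlap with Dlx5 went the other way at equal length in row order, at 42.5% for Sp7mut and 46.8% for Sp7 (Sp7 higher on 17 of 20 chromosomes, exact sign test p = 0.00258), and over all regions at 68.3% and 84.4% (Sp7 higher on 20 of 20). By width the shares were 16.3% and 16.5% (10 chromosomes each way, exact sign test p = 1). Over all regions the gap was not seen without replicate 2 of each group, at 68.1% for Sp7mut and 67.5% for Sp7. Without replicate 1 the shares were 65.7% and 84.8%. Whole single lists gave overlapping ranges, 65.7% to 68.7% and 66.5% to 85.0%. At equal length in row order single lists gave 38.3% to 43.1% and 35.9% to 49.2%, so that the gap there lay within the spread between replicates. For Sp1 the single lists gave 26.1% to 32.3% for Sp7mut and 18.1% to 24.3% for Sp7 there, but the ranges overlapped over the first 2500 rows (21.2% to 27.8% and 14.4% to 22.6%) and over whole lists (33.6% to 70.0% and 25.5% to 61.6%). These ranges pool the Sp1 lists. Against the same Sp1 list, both Sp7mut lists lay above both Sp7 lists at each of these lengths. Sp7mut and Sp1 shared an input library that Sp7 did not use, so input and factor cannot be separated here.

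Within Sp7mut, Dlx5 was met more often than Sp1 in row order, by 12.2 percentage points at equal length (18 of 20 chromosomes, exact sign test p = 0.000402). Over the top 5019 regions by width the direction turned, at 16.3% for Dlx5 and 24.8% for Sp1, and over all regions the difference of 28.3 points turned to -2.18 without replicate 1 of each group.

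In primary osteoblasts, Sp7 regions coincided with cell line Sp7, Dlx5 and Sp7mut regions and rarely with Sp1 regions. Of the 2097 primary Sp7 regions, 69.1% overlapped a cell line Dlx5 region, 48.9% an Sp7mut region, 39.6% a cell line Sp7 region and 4.53% an Sp1 region. Without replicate 1 of each group, which left the longer Sp1 list alone, the share with Sp1 was 26.1%, and with control peaks kept it was 7.49%. Dlx5 exceeded Sp1 on 20 of 20 chromosomes (exact sign test p = 1.91e-06), also among the first 5019 regions, where the shares were 50.2% and 1.72% of the same 2097 regions. Among the first 1000 regions of each list, 1 primary Sp7 region met an Sp1 region, which did not exceed random placement (permutation p = 0.149).

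Sp7 was bound in both cell systems at 831 cell line Sp7 regions, and 814 of these were Dlx5 regions. Primary Sp7 regions that cell line Sp7 also met had a Dlx5 region in 97.8% of cases, against 50.2% of the others. No cell line group met 605 of the primary regions, and Dlx5 alone met 388. Over all regions and among the first 5019 in row order, of which primary Sp7 has only 2097, primary Sp7 regions met Dlx5 more often than cell line Sp7, by 29.4 and 10.5 percentage points (20 of 20 chromosomes each, exact sign test p = 1.91e-06). Among the first 1000 regions the shares were 37.9% and 32.1%. The first 5019 rows of the single lists gave 46.5% and 56.4% for Dlx5 and 33.0% and 42.6% for Sp7. Pairs of single lists, kept to at most that length, gave ranges that overlapped when pooled, 38.8% to 50.6% and 29.6% to 38.9%. Within each primary list, both Dlx5 shares lay above both Sp7 shares. They were 43.1% and 50.6% against 30.8% and 38.9% in replicate 1, and 38.8% and 45.6% against 29.6% and 36.3% in replicate 2. Over the top 5019 regions by width, a step that shortened the Dlx5 list and not that of Sp7, the order turned to 6.96% and 39.6%.

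Regions were spread over the chromosomes in different ways. Sp1 regions were densest on gene-rich chromosomes: over the 19 autosomes, regions per Mb rose with protein-coding genes per Mb, counted in GRCm38.p6 (Pearson r = 0.840, Spearman rho = 0.847, permutation p = 3e-05 and 1e-05, the latter the smallest possible, adjusted 0.0003 and 0.0001 over 10 relations). Without the 2 chromosomes farthest from the median gene density, r was 0.913. In primary Sp7 regions no such relation was detected (r = -0.00703, rho = -0.114, permutation p = 0.976 and 0.641, r = 0.133 without these chromosomes). Cell line Sp7 passed the test (r = 0.50, rho = 0.544, permutation p = 0.0291 and 0.0175, adjusted 0.0491 and 0.0291, r = 0.667 without them). So did Sp7mut (r = 0.617, rho = 0.570, permutation p = 0.00511 and 0.0118, adjusted 0.0170 and 0.0291, r = 0.773 without them). Dlx5 missed the threshold after adjustment (r = 0.477, rho = 0.468, permutation p = 0.0392 and 0.0438, adjusted 0.0560 and 0.0626, r = 0.655 without them). Tested directly, the ratio of Sp1 to Dlx5 regions rose with gene density (r = 0.765, rho = 0.768, permutation p = 0.0001 and 0.0003, adjusted 0.0003 and 0.0009 over 6 relations, r = 0.634 without them), and so did the ratio of Sp1 to primary Sp7 regions (r = 0.799, rho = 0.884, permutation p = 4e-05 and 1e-05, adjusted 0.00024 and 6e-05, r = 0.774 without them). The ratio of Sp1 to cell line Sp7 regions did not pass the test (r = 0.325, rho = 0.212, permutation p = 0.173 and 0.382, adjusted 0.207 and 0.459, r = 0.0338 without them), nor did that of Sp7mut to cell line Sp7 (r = 0.0371, rho = -0.0474, permutation p = 0.878 and 0.847, adjusted 0.878 and 0.847, r = -0.155 without them). The ratios of cell line Sp7 to primary Sp7 (r = 0.504, rho = 0.581, permutation p = 0.0290 and 0.0104, adjusted 0.0579 and 0.0155, r = 0.615 without them) and to Dlx5 (r = 0.458, rho = 0.611, permutation p = 0.0490 and 0.00682, adjusted 0.0735 and 0.0136, r = 0.575 without them) passed by rank and not by Pearson correlation. Sp1 was mapped only in the cell line, so factor and cell system differ together in its comparison with primary Sp7.

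**Figure D4:**
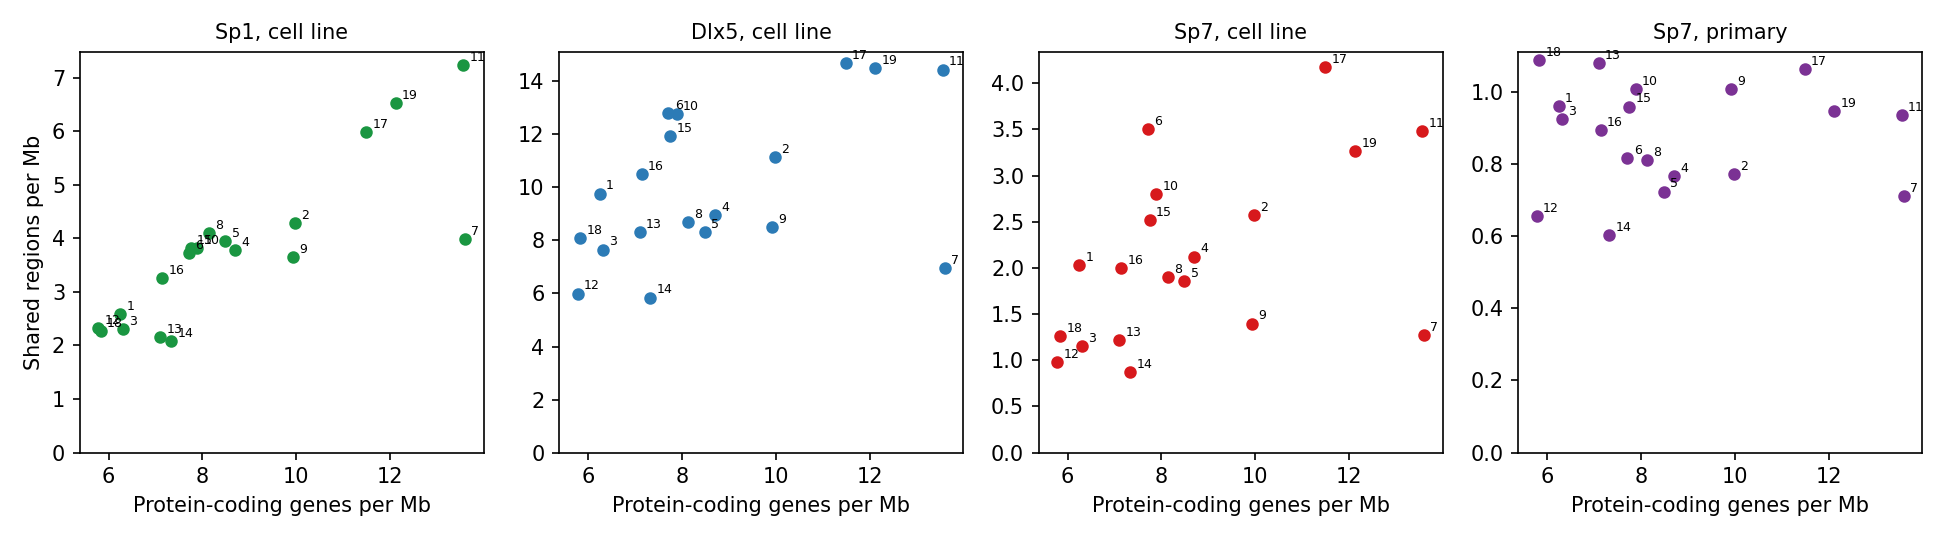
Regions found in both replicates per Mb (vertical axis, from 0) against protein-coding genes per Mb of GRCm38.p6 (horizontal axis) for the 19 autosomes, each point labelled with its chromosome, in 4 groups. Sp1 regions follow gene density (r = 0.840), and no such relation was detected in primary Sp7 regions (r = -0.00703), where both factor and cell system differ.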

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

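Among the tests in this part, only that on row order was set before its result was seen; the others, and all comparisons in row order, were chosen after. The excess of Dlx5 over Sp1 among partner regions differed between cell systems in some settings only. Among the first 5019 regions in row order, of which primary Sp7 has only 2097, it was 48.5 percentage points for primary and 26.3 for cell line Sp7, a difference of 22.1 (16 of 20 chromosomes, exact sign test p = 0.0118). With every list shortened to 2097 regions the difference was 0.286 (p = 0.824, exact sign test), and among the first 1000 it turned to -4.3, from 37.8 and 42.1 (p = 0.503, exact sign test). Over the top regions by width it was 3.38 and did not pass the test (p = 0.263, exact sign test). Over all regions, on lists of different lengths, it was 10.4, from 64.5 and 54.1, and passed the test (16 of 20 chromosomes, p = 0.0118, exact sign test). Without replicate 1 of each group the shares with Dlx5 and Sp1 were 75.7% and 26.1% for primary and 84.8% and 61.4% for cell line Sp7. Without replicate 2 they were 66.9% and 4.81% for primary and 67.5% and 25.1% for cell line Sp7. Whether the excess differs between cell systems is left open. The excess also differed between cell line Sp7 and Sp7mut, at 26.3 and 12.2, a difference of 14.1 (19 of 20 chromosomes, exact sign test p = 4.01e-05). Among the first 1000 regions this difference was 9.9 (16 of 20 chromosomes, p = 0.0118, exact sign test), and over the top regions by width 9.11 (18 of 20, p = 0.000402, exact sign test). Cell line Sp7 shared its input library with Dlx5, and Sp7mut shared another with Sp1, so input and factor cannot be separated in this difference.

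Sp7 regions met Dlx5 regions more often than Sp1 regions. Over whole lists, 18.0% of the 23688 Dlx5 regions and 17.1% of the 8942 Sp1 regions met an Sp7 region. Per partner region these rates were close, so the gap over whole lists went largely with the length of the Dlx5 list. The exact part that comes from length was not measured. Among the first 5019 regions in row order the gap was 26.3 percentage points at equal length, though by width it was 0.578; row order tracked between replicates with a Spearman correlation of at least 0.680, which argues against an arbitrary order. An input library shared by Sp7 and Dlx5 as the whole cause is argued against by primary Sp7, which had an input of its own and a gap of 48.5 (37.8 among the first 1000 regions). The Dlx5 and Sp1 lists still had different inputs in that comparison, so an effect of input on either partner list stays open. Binding of Sp7 at Dlx5 sites, and open chromatin that each factor meets for itself, stay open and were not told apart by any test here.

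Sp7mut regions met Sp1 regions more often than Sp7 regions did. The gap was 9.71 percentage points over all regions and 9.82 at equal length. A longer Sp7mut list does not by itself raise the share of its own regions that meet Sp1. Equal length set 5019 of 8203 Sp7mut regions against all Sp7 regions, so this comparison says little on list length. On spread between replicates, the lowest pair of single lists for Sp7mut lay 1.73 points above the highest for Sp7 at equal length. Over the first 2500 rows the pooled pairs overlapped, at 21.2% to 27.8% and 14.4% to 22.6%, as they did over whole lists. Against the same Sp1 list, both Sp7mut lists lay above both Sp7 lists at each of these lengths. Over the first 2500 rows, Sp1 replicate 1 gave 23.2% and 21.2% against 19.4% and 14.4%. Sp1 replicate 2 gave 27.8% and 25.5% against 22.6% and 16.4%. This argues against spread between replicates as the cause, within the limit of 2 lists per group. The shared input library and the mutation cannot be told apart, because Sp7mut and Sp1 had the same input: 41.7% of Sp7mut regions without Sp7 met Sp1, against 37.9% of those with Sp7 (18 of 20 chromosomes, exact sign test p = 0.000402), which either could give. At equal length in row order these were 32.3% and 28.8%, which did not pass the test (14 of 20 chromosomes, exact sign test p = 0.115).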

How the results depend on the processing

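The contrasts between partners and all settings by row order were chosen after seeing the data. Of 45 alternatives for these contrasts, 33 kept their direction and their side of the threshold, 5 reversed, 6 passed it anew and 1 lost it. Tests against random placement pass for nearly any share, so that 140 of 141 kept their call, and say little on stability: of 110 alternatives for overlap shares, 45 changed the share by more than 1.5 times. Of 25 counts of regions, which have no test, 16 changed by less than that. In row order, primary Sp7 with Sp1 among the first 1000 regions was 0.1% and lost its call (permutation p = 0.149), at 1 region. With control peaks kept it was 7.49%, against 4.53%. With an overlap of at least 50% of both peaks the shares with Sp1 were lower, at 17.3% for Sp7, 21.8% for Sp7mut, 4.54% for Dlx5 and 1.67% for primary Sp7. Shares with Dlx5 were lower too, at 66.3% for Sp7, 53.1% for Sp7mut and 60.4% for primary Sp7. Counts of regions found in both replicates were lower with the wider 50% of each list: 602 for primary Sp7 and 1400 for Sp7, 6574 for Dlx5, 2657 for Sp1 and 2263 for Sp7mut in the cell line. The shares fell as well, to 28.4% for Sp7 with Dlx5, 13.6% with Sp1 and 22.4% with Sp7mut, and for primary Sp7 to 8.97% with cell line Sp7, 15.4% with Dlx5, 1.99% with Sp1 and 10.5% with Sp7mut. Sp7mut fell to 13.9% with Sp7, 24.1% with Dlx5 and 15.9% with Sp1, and Dlx5 to 5.16% with Sp1. Leaving out a replicate, so that no second peak was needed, gave 5976 to 18464 regions for cell line Sp7, 30061 to 39628 for Dlx5, 10371 to 27992 for Sp1 and 10386 to 14666 for Sp7mut. Ranked by width at equal length, the excess of Dlx5 over Sp1 was 0.578 percentage points for cell line Sp7 and no longer passed the test. It turned to -8.53 for Sp7mut. The excess of Dlx5 over cell line Sp7 in primary Sp7 turned to -32.7. There the Dlx5 list was cut from 23688 to 5019 regions and its share fell from 69.1% to 6.96%. The cell line Sp7 list was not cut and its share stayed at 39.6%. This turn thus came from shortening Dlx5 alone, by a rank that did not follow replicate overlap. For the other 2 changes the part of unequal shortening was not measured. For Sp7mut, the excess of Sp7 over Sp1 was 2.69 points and not past the threshold over all regions. It passed with an overlap of at least 50% of both peaks (13.3), at equal length by width (15.6) and in row order (28.8), among the first 1000 regions (47) and with the earlier 50% of each list (14.5), and it turned to -1.99 with the wider 50%. Leaving out a replicate it ranged from -36.3 to 31.8, and the excess of Dlx5 over Sp1 in Sp7mut from -2.18 to 29.7; the cause was not tested. Pairing by replicate number was not seen (correlations of same-numbered deviations from -0.0727 to 0.113). Peaks in both or neither list of a group have no deviation, which can weaken these correlations, so pairing is not excluded. As a replicate block, the mean over same-numbered lists, the shares were 76.2% for Sp7 with Dlx5, 43.6% with Sp1 and 58.7% with Sp7mut, 41.2% for primary with cell line Sp7, 17.7% for primary Sp7 with Sp1 and 20.5% for Dlx5 with Sp1 (11.6% over all regions). All 11 such shares lay above random placement (permutation p = 0.00498, the smallest possible); contrasts were not tested under it. Depth is unknown, so a region missing from a list is not shown to be unbound.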

Other observations

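Few peaks lay on the X chromosome. Peaks per Mb on X were between 0.0543 and 0.230 of those on the autosomes over the 10 tagged lists. The lowest values were 0.0543 and 0.0588 in Sp7mut, and the highest were 0.194 and 0.230 in Sp1. The controls gave 0.251 from 3 peaks on X in wild type and 0.228 from 4 in GFP. On Y, replicate 2 of primary Sp7 had 18 peaks and replicate 1 had 0.

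Few of the Sp7mut regions that Sp7 did not meet were Sp7 regions in primary cells, but those leading in row order were. Of the 4696 regions of this class, 268 (5.71%) were primary Sp7 regions, against 21.6% of the Sp7mut regions that Sp7 met (20 of 20 chromosomes, exact sign test p = 1.91e-06). All 5 of the leading regions of this class in row order, among them chr17:45210232-45210409 and chr1:92537839-92538010 (mm9), were primary Sp7 and Dlx5 regions. By width, 0 of the 5 leading regions were primary Sp7 regions. Overlap of Sp7mut regions with Sp7 fell from 87.4% in the first 20% of the list to 11.7% in the last 20%. Overlap with primary Sp7 fell from 35.9% to 3.05% in the same way. Sp7mut regions with and without Sp7 were not compared at matched row positions.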
